A study of Caenorhabditis elegans with 2 samples.

How the data were processed

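Chromatin immunoprecipitation and sequencing of eGFP-tagged GMEB-1 was done on whole mixed-sex L2 larvae of strain OP343, which carries the integrated transgene wgIs343 in an unc-119 mutant background. The labels number 2 biological replicates. Per the labels, both belong to 1 group, so there is no comparison between groups.

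The files are lists of regions in the narrowPeak layout, in builds ce11 and ce10. Per the readme deposited with the samples, the relaxed list of each replicate was called from its alignments and a control, the pooled list from both alignments and the control, and the IDR list from these lists. The same control is listed for both replicates. The relaxed lists deliberately include background regions. The caller, the aligner, the IDR threshold and the number of reads are not given in the sources used here, so depth is unknown and no depth-based interval is given. The deposited signal of each region is the value that the authors' caller gave it. The deposited −log10 q value of each region reached a ceiling in every IDR region (4.09), so regions were ranked by signal. The scale of the signal differed between the replicates, with maxima of 191.1 and 1996, so it was used only to rank, describe or filter within a list.

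The ce11 lists were analysed with WBcel235, which the reference's own notes equate with ce11, and with Ensembl release 115. No region ended beyond a chromosome. Coordinates are 1-based positions in that build, and the ce10 lists were compared by number and value alone. Sorted by rank, the signals of the IDR lists of the builds differed by at most 1.37%. The regions of the IDR list included 11 repeated intervals with different summits, and no summits lay within 100 bp of one another.

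Replicates were compared by the share of the 3909 highest-ranked regions that overlapped by at least 1 bp, with 10000 circular shifts per chromosome. A promoter ran from 1000 bp upstream to 200 bp downstream of any protein-coding transcript start, and a gene was called bound if an IDR summit lay in it. Positions of summits were set against 10000 circular shifts. Of 33 gene lists written before the data were examined, 32 were tested with Fisher's exact test (two-sided) and Benjamini-Hochberg adjustment, and the list of GMEB genes served only for naming. Lists were matched by gene symbol. All written names matched except in the autophagy list (24 of 25), the heterochronic list (18 of 23, where the unmatched names include microRNA genes) and the chromatin list (38 of 40). Lists defined by a symbol pattern have no such count. Genes that share a promoter or a cluster are not independent in these tests. Lists can also share a gene, as the chromatin and germline lists share mes-2. Motif windows reached 50 bp to either side of the summit and were compared with 9170 windows at those of the 10000 lowest-ranked pooled regions that lay at least 1000 bp from an IDR summit. The 6-mers were found on I, III and V and tested on II, IV and X. Tests treat regions and genes as units, and they do not measure the spread between animals.

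Genes were named by a rule fixed before the data were examined: the genes nearest to the 15 summits of highest signal in promoters, the GMEB genes and unc-119, the 4 strongest bound members of each list with a raised share, and 2 of each other developmental or tissue list. The alternatives were a promoter of 500 and 100 bp or of 2000 and 500 bp, the 1954 strongest IDR regions, each replicate's own top 3909 regions, the nearest start only, lists without 2517 operon-like genes (a same-strand upstream neighbour within 300 bp), permutation within deciles of upstream distance (100000 draws), shifts within 100000 bp, other overlap rules, windows and motif backgrounds, and other distances for non-coding genes and transgene loci. For reciprocal overlap the shifts used the 1 bp rule, which makes that p an upper bound. Odds ratios stratified by GC count (Mantel-Haenszel) were added after seeing the data.

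The scripts were tested on simulated data. Of 3909 simulated summits with an expected promoter share of 70.5%, 70.9% were recovered, and 5 of 100 sets of uniform summits had p under 0.05. Of 32 simulated gene lists, all 10 raised lists and 1 of 22 others were called. These lists were of equal size, shared no genes and were bound independently. They did not cover shared promoters, clusters or the range of real list sizes. An implanted 6-mer ranked 1 and passed on the held-out chromosomes, and 0 of 10 passed with nothing implanted. In that simulation summits and background were both uniform positions, so it did not cover the GC difference between the real summit and background windows. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.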

Results

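Binding of GMEB-1 was measured by chromatin immunoprecipitation and sequencing in whole Caenorhabditis elegans larvae of the L2 stage, in a strain that carries an eGFP-tagged gmeb-1 transgene. GMEB-1 is a worm relative of the mammalian glucocorticoid modulatory element binding proteins, which bind DNA through a SAND domain. There was 1 group with 2 biological replicates, and no other genotype or stage to compare it with. The deposited lists give regions, not reads, so the depth of each replicate is unknown. The list that passed the irreproducible discovery rate (IDR) threshold, deposited as the optimal list, held 3909 regions in the current genome build and 3902 in the older build. Its regions had a median width of 336 bp, from 84 to 3570 bp. Their signal, a value the authors' caller gave each region, ranged from 38.7 to 2077 with a median of 68.4. All 3909 regions were the highest-ranked regions of the list called on both replicates together. Replicate 1's own relaxed list overlapped 3275 of them, so not all were found in both replicates. The IDR summits were spread over every nuclear chromosome, from 32.3 per Mb on V to 51.7 per Mb on III.

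The first comparison was between the replicates. The 2 strongest regions lay upstream of the ribosomal protein gene rpl-3 and of cdc-48.1. They were near the top of both lists, at ranks 7 and 14 in replicate 1 and at ranks 1 and 2 in replicate 2. Over the 15 summits of highest signal in promoters, ranks ran from 7 to 587 in replicate 1 and from 1 to 15 in replicate 2. Of the 3909 highest-ranked regions of replicate 1, 52.5% overlapped one of the 3909 highest-ranked regions of replicate 2 by at least 1 bp, and 51.9% did in the other direction. Circular shifts along each chromosome gave means of 2.38% and 2.39%, and the one-sided permutation p was 1e-04 in both directions, the smallest that 10000 shifts can give. The IDR list followed replicate 2 more closely than replicate 1, since 93.8% of its regions were among the top regions of replicate 2 and 55.03% among those of replicate 1. In replicate 1 this share fell from 79.4% of the 500 strongest IDR regions to 28.4% of those ranked 3001 or lower. The whole relaxed list of replicate 1 overlapped 83.8% of the IDR regions, and that of replicate 2 overlapped 99.5%. Among genes named below, the summits at sars-2, lep-2, tbb-1, daf-15 and ceh-92 lay in no region of replicate 1's relaxed list. Across the 3001 IDR summits that lay in a region of both relaxed lists, the ranks in the replicates had a Spearman correlation of 0.422 (permutation p = 1e-04), although regions are not independent replicates. The values below therefore rest mainly on regions ranked high in replicate 2.

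**Figure D1:**
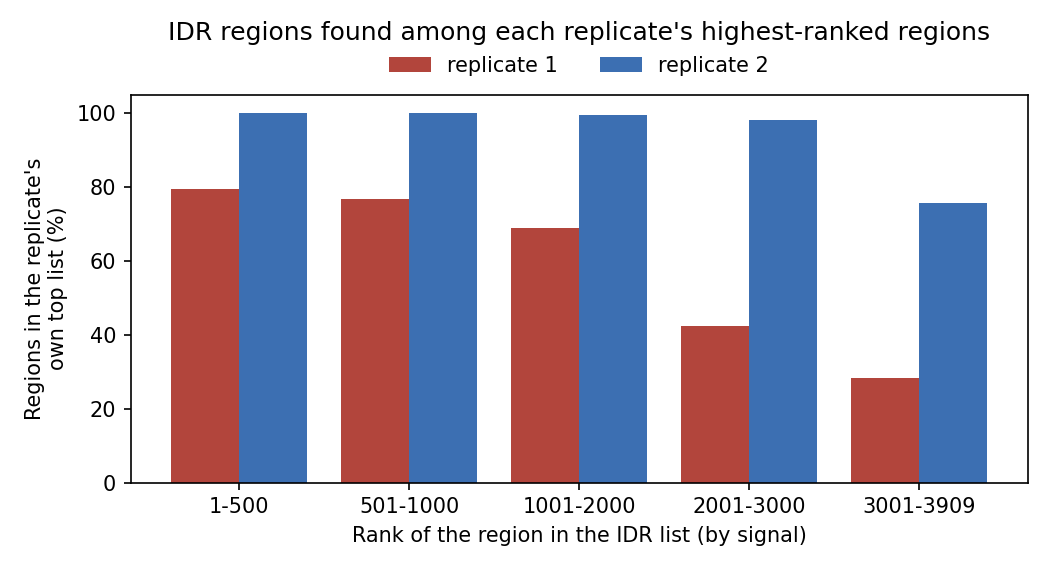
Percent of IDR regions (y axis) that overlap 1 of the 3909 highest-ranked regions of each replicate, by rank in the IDR list (x axis). Replicate 2 holds 100% of the 500 strongest and 75.6% of the weakest class, and replicate 1 holds 79.4% and 28.4%.

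GMEB-1 summits lay close upstream of genes. Of the IDR summits, 65.2% fell from 1000 bp upstream to 200 bp downstream of a protein-coding transcript start, against a mean of 26.1% and a maximum of 33.8% over 10000 circular shifts (one-sided permutation p = 1e-04, the smallest possible). The median distance to the nearest start was 330 bp, and 77.1% of summits were upstream of it. Intergenic sequence held 66.8% of summits against a shift mean of 32.7%, and 5' UTRs held 4.43% against 1.42%. Coding exons held 1.89% against 24.8%, introns 20.03% against 33.9%, and 3' UTRs 1.64% against 3.36%. Each of these shares differed from the shifts with an adjusted permutation p of 0.00024. The promoter share was 90.6% among the 500 strongest summits and 55.8% among those ranked 3001 or lower.

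**Figure D2:**
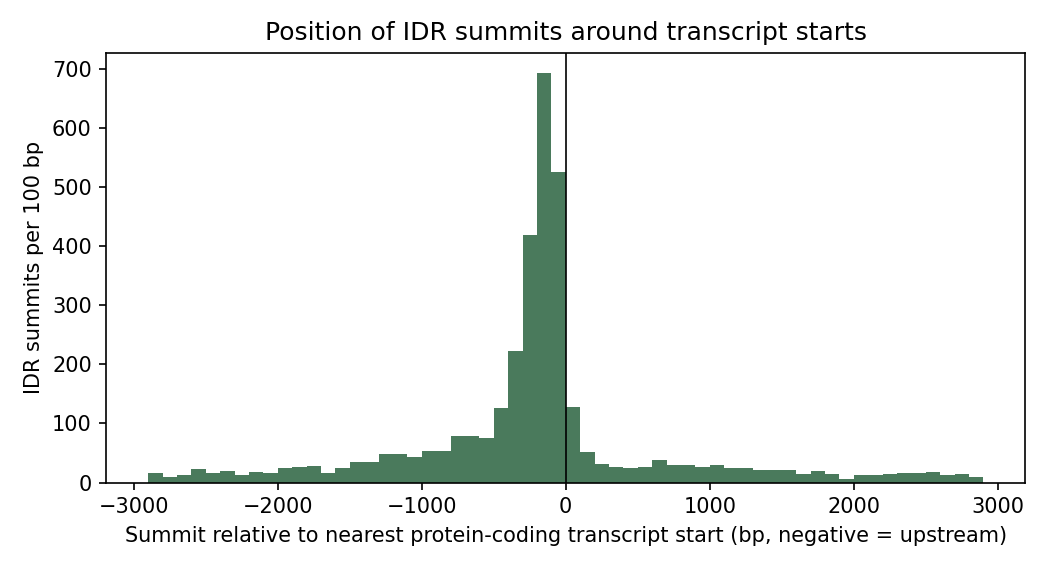
Number of IDR summits per 100 bp (y axis) by position relative to the nearest protein-coding transcript start in bp (x axis, upstream negative). The bars drawn rise to a single peak just upstream of the start, the end bins with 212 upstream and 160 downstream summits at 2900 bp or more are not drawn, and the median distance of all 3909 summits is 330 bp.

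The 15 summits of highest signal in promoters were on chromosomes I to V. The strongest, with a signal of 2077, was at III 3867563, in intergenic sequence 291 bp upstream of the start of rpl-3, a protein of the large ribosomal subunit. It was followed by II 10563578, 171 bp upstream of cdc-48.1, an AAA ATPase that extracts ubiquitinated proteins (signal 1845), and by V 10897375, 232 bp upstream of sec-61.G, a subunit of the translocon (signal 1568). Next came rpl-35 on III (signal 1539), citk-2 on II (1442), eelo-2 on IV (1366), and dld-1 on IV, which encodes dihydrolipoamide dehydrogenase (1319). The summits at the translation initiation factor gene eif-3.C on I, at ddp-1 on III, at T23F6.3 on IV and at C27F2.9 on III had signals of 1272, 1230, 1228 and 1203. The last of the 15 were at the RNA polymerase II subunit gene rpb-11 on II (1195), the alpha-tubulin gene tba-2 on I (1187), F48A11.4 on II (1174) and the elongation factor gene eef-2 on I (1157). Of these 15 summits, 14 were annotated as intergenic and the one at dld-1 lay in a non-coding gene. Several promoters are shared, so the summit at C27F2.9 also lies in the promoter of vps-22.

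A summit in the promoter marked 3267 of 19973 protein-coding genes on nuclear chromosomes, or 16.4%, and these are called bound below. Both samples target GMEB-1 and no other factor was available, so whether the shares below are particular to GMEB-1 was not tested. With the 1954 strongest IDR regions alone the number was 2047. Among 32 gene lists fixed before the data were examined, 16 held more bound genes than other protein-coding genes and 8 held fewer (Fisher's exact test, two-sided, adjusted over the lists).

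Cytosolic ribosomal protein genes had the highest share of the 32 lists in the main setting. Of 81 genes 70 were bound, or 86.4% (odds ratio 33.2, Fisher's exact test adjusted p = 1.42e-42), led by rpl-3, rpl-35, rpl-24.2 and rps-12. The odds ratio was 20.5 in replicate 1 alone and 57.5 without operon-like genes. With the nearest start only it was 6.43, below the proteasome (8.68), replication (7.23), nuclear pore (7.22), translation factor (6.89) and chromatin (6.51) lists. Translation initiation and elongation factors had 28 of 41 bound (odds ratio 11.1, adjusted p by Fisher's exact test 1.79e-12), led by eif-3.C, eef-2, eif-3.B and iff-2, with an odds ratio of 6.47 in replicate 1 alone and 6.89 with the nearest start only. Mitochondrial ribosomal proteins had 29 of 66 bound (odds ratio 4.03, exact test adjusted p = 2.89e-07), with the strongest summits at mrpl-47, mrpl-28, mrps-16 and mrpl-55, and an odds ratio of 7.28 without operon-like genes. Aminoacyl-tRNA synthetases had 12 of 32 bound (odds ratio 3.08, exact test adjusted p = 0.00546), among them vars-1, sars-2, rars-1 and ears-2. The call for synthetases was lost in the narrower promoter window (odds ratio 2.17), with the nearest start only (2.01), and in replicate 1 alone (1.06).

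The lists for protein folding, degradation and membrane traffic were also above other genes. The proteasome had 22 of 33 subunit genes bound (odds ratio 10.3, exact test adjusted p = 7.64e-10), including rpn-11, pbs-1, rpn-3 and rpn-5. Heat shock proteins and chaperones had 32 of 64 bound (odds ratio 5.15, exact test adjusted p = 2.16e-09), including dnj-9, the prefoldin subunit pfd-6 and the chaperonin subunits cct-1 and cct-8. The summit counted for cct-1, 240 bp from its start, is also that of mig-5 in the Wnt list, at 180 bp. Autophagy and lysosome regulators had 11 of 24 bound (odds ratio 4.34, exact test adjusted p = 0.00123), including lgg-2, lgg-1, atg-9 and epg-6. Among the 1954 strongest regions this call was lost, with an odds ratio of 2.31. Vacuolar ATPase subunits had 9 of 21 bound (odds ratio 3.84, exact test adjusted p = 0.00593), including vha-16, vha-8, vha-9 and vha-12. Small GTPases and membrane traffic genes had 34 of 89 bound (odds ratio 3.18, exact test adjusted p = 1.51e-06), including vps-22, rab-18, vps-4 and sec-24.1. In replicate 1 alone the odds ratio was 3.25 for the proteasome (exact test adjusted p = 0.00632) and 8.22 for the vacuolar ATPase. The vacuolar ATPase had 6.20 in the wider promoter, and heat shock proteins and chaperones had 2.40 with the nearest start only.

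The lists for DNA replication, nuclear pores, chromatin, splicing and respiration were above other genes too. DNA replication and cell cycle genes had 22 of 32 bound (odds ratio 11.3, exact test adjusted p = 3.62e-10), including the E2F gene efl-1, the sliding clamp gene pcn-1, the cyclin gene cyb-1 and cdc-6. Nuclear pore proteins had 17 of 26 bound (odds ratio 9.70, exact test adjusted p = 8.42e-08), including npp-19, npp-3, npp-22 and npp-23. Chromatin regulators had 22 of 38 bound (odds ratio 7.07, exact test adjusted p = 2.59e-08), including the histone methyltransferase genes mes-2 and set-16 with lin-53 and mys-1. Splicing factors had 25 of 47 bound (odds ratio 5.85, exact test adjusted p = 2.59e-08), including snrp-3, snr-6, snr-2 and sap-140. The respiratory chain had 37 of 69 bound (odds ratio 5.97, exact test adjusted p = 1.07e-11), including cox-5A, nduf-11, cox-10 and nduv-3. In replicate 1 alone the odds ratio was 4.48 for replication and cell cycle genes, 3.95 for nuclear pore proteins and 3.51 for splicing factors. With the nearest start only it was 7.23 for replication and 3.73 for splicing, and without operon-like genes 9.34 for splicing and 10.8 for chromatin.

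Among developmental and tissue genes, the heterochronic pathway, which times larval development, had 8 of 18 bound (odds ratio 4.098, exact test adjusted p = 0.00720), including nhl-2, lep-2, lin-28 and ain-1. Intestinal genes had 10 of 30 bound (odds ratio 2.56, exact test adjusted p = 0.0294), including the esterase gene ges-1, the GATA factor gene elt-2, erm-1 and pept-1. The heterochronic call was lost in the narrower promoter window (odds ratio 1.86) and among the 1954 strongest regions (2.51). The intestinal call was lost in the narrower window (2.37) and in replicate 2 alone (2.17), where the odds ratio changed little. Among the 1954 strongest regions the intestinal odds ratio was 0.973. In the main setting no difference passed the test for pan-neuronal genes (5 of 25 bound, with ric-19 and tbb-1 strongest), germline genes (5 of 40, mes-2 and cgh-1), muscle genes (3 of 30, unc-45 and unc-52), the Wnt pathway (6 of 32, mig-5 and wrm-1), the insulin, TGF-beta and dauer pathway (7 of 33, daf-15 and rict-1), nuclear hormone receptors (48 of 274, nhr-47 and nhr-142), histones (10 of 59) or P450, glucuronosyltransferase and glutathione S-transferase genes (26 of 185). Other settings gave calls for 3 of these lists. Among the 1954 strongest regions the odds ratio was 0.192 for P450, glucuronosyltransferase and glutathione S-transferase genes (exact test adjusted p = 8.89e-05), which had 0.514 in replicate 1 alone (adjusted p = 0.0302), and 0.539 for nuclear hormone receptors (adjusted p = 0.0193). In the wider promoter the insulin, TGF-beta and dauer pathway had 2.48 (exact test adjusted p = 0.0219).

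The other 8 lists that passed held fewer bound genes. Of 1306 chemoreceptor genes 19 were bound, or 1.45% (odds ratio 0.0701, Fisher's exact test adjusted p = 6.95e-75). C-type lectins had 10 of 237 bound (odds ratio 0.223), insulin-like and neuropeptide genes 3 of 140 (0.111), collagens 9 of 175 (0.275) with col-38 and col-2 strongest, F-box and MATH proteins 30 of 388 (0.423), and homeodomain factors 5 of 86 (0.315) with ceh-38 and ceh-92 strongest. The adjusted p of these 5 lists by Fisher's exact test lay between 2.71e-08 and 0.00747. None of 43 major sperm protein genes (exact test adjusted p = 0.00123) and none of 28 hypodermis and seam genes (exact test adjusted p = 0.0137) was bound. The hypodermis and seam call was lost in replicate 1 alone, where the odds ratio was 0.893. It was also lost in the narrower window, with the nearest start only and among the 1954 strongest regions, although the odds ratio stayed at 0 in each. In replicate 1 alone the odds ratio was 0.142 for chemoreceptors and 0.218 for insulin-like and neuropeptide genes, which had 0.0465 in the narrower and 0.229 in the wider promoter, and homeodomain factors had 0.154 in the narrower promoter and 0.208 among the 1954 strongest regions.

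**Figure D3:**
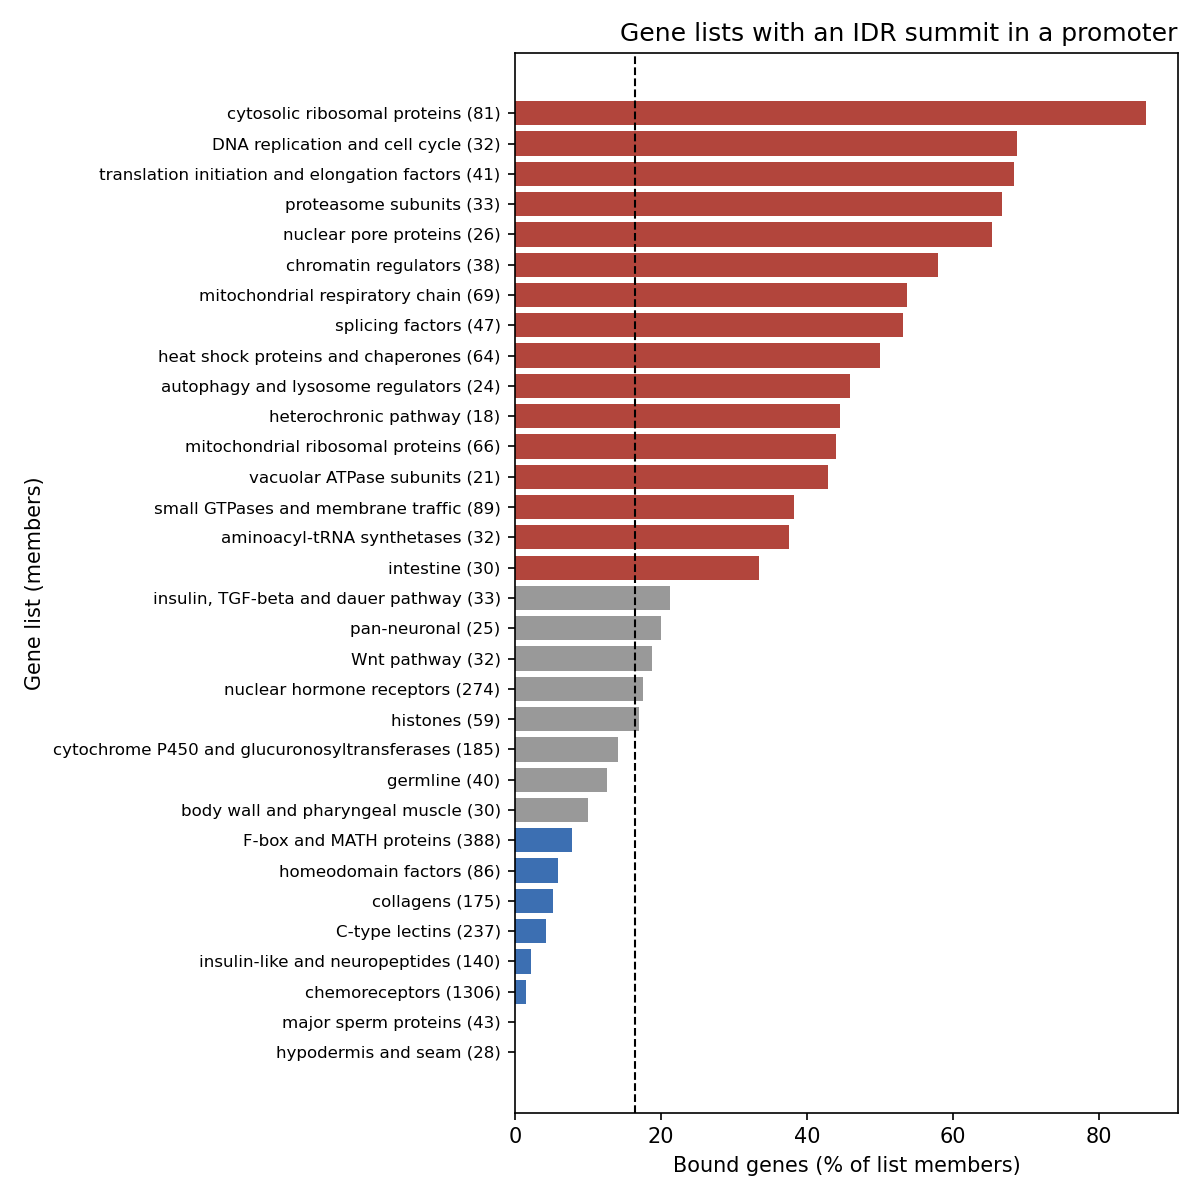
Percent of the members of each gene list that were bound (x axis), with the number of members beside the name of each list (y axis). Red bars are lists above and blue bars lists below other genes at an adjusted p under 0.05, grey bars did not pass, and the dashed line is the 16.4% of all protein-coding genes. In the main setting drawn here, cytosolic ribosomal proteins are highest at 86.4%.

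Genes on the X chromosome were bound less often than autosomal genes in the IDR list. Of 2731 genes on X 12.1% were bound, against 17.03% of 17242 autosomal genes (odds ratio 0.672, 95% interval 0.593 to 0.759, Fisher's exact test p = 3.18e-11). In replicate 1 alone no difference was detected, with an odds ratio of 0.994 (0.875 to 1.13, exact test p = 0.949), and in replicate 2 alone the odds ratio was 0.635. Among the 1954 strongest regions it was 0.389 (0.321 to 0.468, exact test p = 1.16e-29). These regions follow replicate 2 closely, so 0.389 cannot be read apart from that replicate. Genes in the arms of the autosomes, the outer 25% at each end, were bound less often than those in the centres, 15.6% against 18.1% (odds ratio 0.836, 0.770 to 0.907, exact test p = 1.27e-05).

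The sequence at summits was compared with windows at the 10000 lowest-ranked regions of the pooled relaxed list, less those within 1000 bp of an IDR summit. The ACGT core that mammalian GMEB proteins bind was present in 26.1% of 3909 windows reaching 50 bp to either side of the summit and in 16.5% of 9170 background windows (odds ratio 1.79, 95% interval 1.63 to 1.96, Fisher's exact test p = 1.74e-35). Summit windows were richer in GC, at 44.1% against 33.9%, and after stratifying by GC count, a test chosen after seeing the data, the odds ratio was 1.36 (1.23 to 1.499). The longer sites TACGTA (0.793% against 0.687%, exact test p = 0.499) and TTACGTAA (0.0767% against 0.0436%, exact test p = 0.434) did not differ in the main setting, although TACGTA had an odds ratio of 1.53 in replicate 1 alone (1.01 to 2.31, exact test p = 0.0404). GACGTC was at 2.20% against 1.44% (odds ratio 1.54, exact test p = 0.00274), and this call was lost in the widest windows (1.22, exact test p = 0.0605) and against windows beside the summits (1.21, exact test p = 0.179). ACGT was present at 18.2% of the 500 strongest summits and at 29.6% of those ranked 1001 to 2000, a difference that was not tested.

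Other sequences separated summits from background more strongly. The 10 best 6-mers found on chromosomes I, III and V were all enriched on II, IV and X. They are not 10 independent sequences, since many of them overlap. AGAGAC, CGTCTC read on the other strand, AGACGC, GACGCA, ACGCAG and CGCAGA follow one another in steps of 1 base. GAGAGA and AGAGAG also differ by a step of 1 base. The held-out odds ratios were 10.9 for ACGCGC, 7.43 for GAGCGC, 6.77 for ACGCAG, 6.90 for AGACGC, 6.70 for GACGCA, 5.61 for CGTCTC, 5.58 for CGCAGA, 5.49 for AGAGAC, 5.05 for AGAGAG and 4.61 for GAGAGA, and the largest adjusted p by Fisher's exact test was 3.99e-48. Stratified by GC count, a test chosen after seeing the data, all 10 odds ratios were lower but above 1, from 5.45 for ACGCGC, 3.77 for GAGCGC and 3.25 for ACGCAG down to 2.47 for CGTCTC. In replicate 1 alone and in the widest windows neither ACGCGC nor GAGCGC was among the 10 best, while ACGCGC had 16.5 among the 1954 strongest regions and GAGCGC had 11.2 there, 12.3 in the narrowest windows and 11.7 against random promoter positions. One or more of the 10 was present in 55.3% of 1861 held-out summit windows and in 16.8% of 4196 background windows.

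Genes for small structural RNAs were near summits more often than in shifted positions. Of the IDR summits, 4.81% lay within 200 bp of a tRNA gene against a shift mean of 0.261%, 0.870% within 200 bp of an snRNA gene against 0.0647%, and 2.15% within 200 bp of a snoRNA gene against 0.188% (permutation, adjusted p = 0.000333 for each). Genes of miRNAs, lincRNAs and other ncRNAs were also above the shifts, at 2.62, 1.93 and 3.74 times the shift mean. The shifts do not keep the summits' preference for intergenic sequence, which was itself 2.04 times the shift mean. Ratios near that value, as for lincRNAs and miRNAs, need not be particular to the class. Among the 1954 strongest regions the calls for miRNAs and lincRNAs were lost (permutation adjusted p = 0.0814 and 0.659). The miRNA ratio did not fall there (2.68 times), while that of lincRNAs did (1.28 times). Pseudogenes (0.895% against 3.84%) and piRNA genes (1.38% against 3.13%) were below, each with a permutation adjusted p of 0.000333. No summit lay near an rRNA gene, where the shifts gave 0.0168%. Where the summit had to lie inside the gene, tRNA and other ncRNA genes remained above the shifts. The calls for snRNA (4.998 times the shift mean, permutation adjusted p = 0.0908) and snoRNA genes (2.58, permutation adjusted p = 0.138) were lost. Those for miRNA (1.03 times), lincRNA (1.70 times, permutation adjusted p = 0.132) and piRNA genes (0.318 times, permutation adjusted p = 0.0908) were lost too, although only the miRNA ratio came close to 1. Antisense RNA genes passed only within 500 bp (2.23 times, permutation adjusted p = 0.00711). At that distance the ratio to the shift mean fell from 18.4 to 9.40 for tRNA, from 13.4 to 6.93 for snRNA and from 11.4 to 7.01 for snoRNA genes. It was 2.36 for other ncRNAs, 2.98 for miRNAs, 2.25 for lincRNAs, 0.396 for pseudogenes and 0.711 for piRNA genes.

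The loci carried by the strain were examined last. The gene gmeb-1 lies at II 19538 to 22169, and none of the 4 lists had a summit in it or within 1 kb. It lies in a stretch at the chromosome end that is empty in every list, since the first region on II starts at 41976 in the pooled list, 43373 in replicate 1, 41977 in replicate 2 and 43663 in the IDR list. No IDR summit was at gmeb-2 or gmeb-3 either. The rescue marker unc-119, at III 10902641 to 10908935, had no summit in its promoter but held 4 IDR summits in its body, 2 in introns and 2 in coding exons, the strongest at III 10905300 with a signal of 283.9. The summits at 10905300, 10907889 and 10908714 ranked 5, 38 and 185 in replicate 1 but 491, 925 and 3321 in replicate 2. That at 10904596 ranked 2585 in replicate 2 and lay in no region of replicate 1's relaxed list. Within 20 kb of unc-119 the IDR list had 5 summits, a number that 7.69% of random genic windows of that width reached. The 5 within 10 kb were reached by 1.77% and the 6 within 40 kb by 18.07%. Within 20 kb of gmeb-1 it had 0, as did 24.5% of random windows, and within 10 kb it had 0, as did 43.3%. Within 40 kb it had 1.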

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

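The stratification by GC count was chosen after seeing the data, and all other alternatives were fixed before the data were examined. The replicate overlap, the promoter share, the comparison of arms with centres and ACGT kept their direction and their side of the threshold under every alternative run for them, and the counts of raised lists (13 to 17) and lowered lists (7 to 9) stayed within 1.5 times. X against autosomes did not: its odds ratio was 0.389 among the strongest regions and ranged from 0.635 to 0.994 when 1 replicate was left out. It was not past the threshold in replicate 1 alone, and the cause was not tested. In a comparison not planned in advance, 23.3% of 614 genes marked in replicate 1 only were on X. Of 1541 genes marked in replicate 2 only, 9.09% were (odds ratio 3.04). Among the strongest IDR regions, cut to 1954 by construction, 2047 genes were bound. With summits required inside the gene, 2 non-coding classes remained above the shifts. The pooled list had 0 regions per 10 kb within 10 kb of gmeb-1 and 2.25 within 40 kb, against 0.237 within 20 kb, since its first region on that chromosome lies near the edge of the window. Depth is unknown and limits what can be said of weak regions.

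Odds ratios that changed direction belonged, with the intestinal list as the exception, to results that did not pass the test in the main setting, and the cause was not tested. For histones they were 0.776 in the wider promoter, 0.912 in replicate 2 alone (1.91 in replicate 1 alone), 0.967 with the nearest start, 0.885 without operon-like genes, and 0.696 (observed over expected) within distance deciles. For nuclear hormone receptors they were 0.953 in the narrower promoter, 0.539 (past the threshold) among the strongest regions, 0.949 in replicate 1 alone and 0.890 in replicate 2 alone. Among the strongest regions the intestinal list had 0.973. In the narrower promoter the Wnt pathway had 0.930 and the insulin, TGF-beta and dauer pathway 0.898, which had 2.48 (past the threshold) in the wider promoter. Germline genes had 1.06 in replicate 1 alone and 0.723 in replicate 2 alone, and P450, glucuronosyltransferase and glutathione S-transferase genes 1.12 with the nearest start, but 0.192 among the strongest regions and 0.514 in replicate 1 alone, both past the threshold. TACGTA had 0.934 in the widest windows and 0.697 against random promoter positions, but 1.53 (past the threshold) in replicate 1 alone, and TTACGTAA had 0.966, 0.502 and, in replicate 1 alone, 0 (1.76 in replicate 2 alone).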

Other observations

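The comparison of operon-like genes, the count of summits per gene for unc-119 and the use of empty windows at gmeb-1 as a test were chosen after the results were seen, while the windows around both loci were fixed before the data were examined, and the tests of unshared regions and of composition were written before their values were seen. Operon-like genes, with a same-strand neighbour ending within 300 bp upstream, were bound in 10.6% of 2517 cases, against 17.2% of 17456 other genes (odds ratio 0.572, 95% interval 0.499 to 0.654, Fisher's exact test p = 3.06e-18). An IDR summit lay within 200 bp of 32.8% of 612 tRNA genes, 20.9% of 129 snRNA genes and 24.3% of 346 snoRNA genes. The best rank of a summit near a tRNA gene was 630, while the best near an snRNA gene was 96. The summit at ges-1, singled out after its values were seen, ranked 1 in replicate 1 and 113 in replicate 2.

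The 1857 top regions of replicate 1 that overlapped no top region of replicate 2, called unshared here, differed from the shared ones. Of the unshared regions 37.05% had the summit in a promoter, above every circular shift (maximum 30.6%) and below the 64.1% of shared regions. The shifts stand for background placed without regard to genes, so such background cannot be the whole source. They cannot exclude background of a weaker library that itself gathers at promoters. Coding exons held 21.6% of the unshared and 3.22% of the shared regions, where shifts of the IDR summits gave a mean of 24.8%. Of the 1882 top regions of replicate 2 that overlapped no top region of replicate 1, 67.3% had the summit in a promoter and 1.91% in a coding exon, close to the shared ones. Of the unshared regions 57.1% overlapped replicate 2's whole relaxed list, against a highest shift of 24.3%, which is consistent with many of them lying below the rank limit in replicate 2. No biological explanation was tested, since the replicates belong to 1 group.

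Against the low-ranked background, the ACGT odds ratio stratified by GC count was 1.36 with an interval of 1.23 to 1.499. GC content alone therefore does not account for all of the enrichment over that background. Over all IDR summits and without stratification, the odds ratio was 1.33 against random promoter positions and 1.41 against windows beside the summits. Both had less GC than the summits (35.2% and 36.1% against 44.1%). Stratification was not run against them, so GC and promoter sequence together were not tested. Base composition stays open. Of the other 4-mers with a CpG, an A and a T, CGTA had a stratified odds ratio of 1.32 (1.21 to 1.45), which overlaps the interval of ACGT, while CGAT had 0.952 and TCGA 0.807. The enrichment may therefore not be specific to the ACGT core. The 10 enriched 6-mers had stratified odds ratios from 2.47 to 5.45 on the held-out chromosomes. No biological explanation was tested.

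The 4 IDR summits in unc-119 are a number that 0.165% of protein-coding genes reached within the gene and 1 kb, and 10 of 5440 genes of similar length. A candidate explanation is extra copies of the rescue marker in the strain, although the pattern was found and tested on the same data. The same explanation would raise gmeb-1, where replicate 1 had no region within 10 kb. Of random genic windows 1.12% are empty in that list, 13.5% in the list of replicate 2 and 13.02% in the pooled list. Within 10 kb the gap is therefore unusual only in the list of replicate 1. Within 20 kb, replicate 1 had 0 regions, as did 0.43% of random windows. The pooled list and replicate 2 had 1 region each there, near the edge of the window. At most 1 region was held by 7.37% of random windows in the pooled list and 7.78% in replicate 2. Windows with 0 regions made up 4.27% and 4.62%. The strain carries a tagged gmeb-1 transgene, and no list has a region on II before 41976. The gap therefore cannot show whether extra copies raise the signal at gmeb-1. Whether a filter or poor mapping emptied the chromosome end is unknown.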
